A study of Mus musculus with 18 samples.

How the data were processed

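Gene expression was measured by RNA sequencing in 18 libraries of mouse cells labelled as pulmonary microvascular endothelial cells, the cells that line small lung vessels. The series title speaks of pulmonary vascular smooth muscle cells instead, and the libraries are described here by their sample labels. Per the labels' protocols, cells in 60 mm dishes received 5 ul of a 10 uM stock of scrambled small interfering RNA (siRNA) or siRNA against CYP1B1, by lipid transfection, 2 hours after a medium change. At 24 hours after transfection, 1 uM E2 or 1 uM 16aOHE was added for 24 hours in 5% serum, or vehicle for the third arm. The labels thus gave 6 groups of 3 libraries, scrambled or siCYP1B1 crossed with vehicle, E2 or 16aOHE. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so that p-values measure only the spread between these samples, which may be technical. The labels carry no replicate numbers, and libraries were numbered within a group only to name them. The siRNA sequence is not given in the sources used here.

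The authors deposited 1 table of 15288 genes by 18 libraries. Its deposited values are CPM (counts scaled to the same total of reads assigned to the listed genes), plus an offset of 1e-04 added to every value, since each column summed to 1000001.5 or 1000001.6. TopHat2, Partek and the mm10 genome build are named per the submitters' processing notes, and their versions, the gene annotation and the filters are not given in the sources used here. Gene positions are those of the deposited table on mm10, written 1-based with the stop reduced by 1, because the stop reduced by 1 equalled the RefSeq GRCm38.p6 gene end for 56.7% of the 14902 symbols matched, against 4.13% for the stop as listed. Starts were equal for 57.7%, and 354 symbols were matched only among synonyms. No gene named as mitochondrially encoded was among the rows.

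Low values fell on steps that give the worth of 1 read in each library. From those steps the depth was estimated, and 89.5% to 93.2% of the values came out whole within a tolerance of 0.1 reads. Because the remainder were fractional, the values were not treated as counts, and tests that need whole counts were not run. At this depth 1 CPM stands for about 14.1 reads in the shallowest library and 38.5 in the deepest. The 10 most abundant genes held 2.38% to 2.84% of each library. No columns were identical. Log-scale correlations between libraries were 0.9945 to 0.9978 within groups and 0.9864 to 0.9967 between groups, and within-group pairs differed by 2.41 to 8.07 times sampling noise (chi-square per degree of freedom), which does not tell separate cultures from separate library preparations.

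Values were tested as log2(CPM + 1), so that log2 fold changes understate the change of genes near 1 CPM. Genes with a mean of at least 1 CPM over the 18 libraries were tested (11835 genes), and 3453 fell below. A linear model with 1 coefficient per group was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), so that the groups shared 1 estimate of spread. Benjamini-Hochberg adjustment was made over the genes tested within each of 14 contrasts, with a threshold of 0.05. The contrasts were siCYP1B1 against scrambled in each estrogen arm and averaged over the 3 arms, E2 and 16aOHE against vehicle in each siRNA and averaged over both, 16aOHE against E2 in each siRNA, and the interaction of each estrogen with the siRNA. Adjusted p-values for genes are from limma throughout. Cyp1b1 was also compared by 2-sided exact permutation tests, which for 3 against 3 libraries cannot give a p below 0.1.

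A set of 25 gene lists was fixed before the data were examined, and the 23 with at least 3 tested genes were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. The lists covered estrogen receptors and their target genes, estrogen metabolism enzymes, aryl hydrocarbon receptor targets, NRF2 oxidative stress targets, markers of endothelial, smooth muscle, fibroblast and pericyte, leukocyte, and epithelial and mesothelial cells, the BMP pathway, TGF-beta targets and matrix, interferon response, NF-kB inflammatory genes, cell cycle, p53 targets, cholesterol synthesis, fatty acid metabolism, glycolysis and hypoxia, oxidative phosphorylation, the unfolded protein and amino acid stress response, immediate early genes, the circadian clock, nuclear-retained RNAs and ribosomal proteins. Members were also counted with p-values adjusted over the list alone. Camera was repeated with the correlation estimated from the data.

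Named genes followed a rule fixed beforehand, which left out predicted genes, small RNAs and pseudogene names. It took Cyp1b1 and the estrogen receptors. In the 3 comparisons in which only 1 factor differed from scrambled siRNA with vehicle it took up to 10 genes in each direction with the largest change among called genes whose 3 against 3 values did not overlap, a split that chance gives for 10% of genes. In other contrasts it took up to 5 in each direction, and from each list up to 4 called members with the smallest p, or 2 members where none passed. Where fewer than 3 genes passed, the 3 with the smallest p in each direction were named as not passing.

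Alternatives fixed beforehand were pseudocounts of 0.25 and 4, no filter or a mean of at least 5 CPM, quantile normalization, median-of-ratios factors, robust eBayes, a fit of only the groups compared, an estimated inter-gene correlation, and leaving out each library in turn. Chosen after the data were seen were limma-voom on the estimated reads, the first residual component as a covariate, the first-listed library of each group as a block, and a fit without the first-listed library of every group. The overlap of the E2 and 16aOHE responses was set beside 100 simulated draws of unchanged groups, with and without shared controls. The draws were taken from the residuals of all 18 libraries regardless of group. Transcript lengths, GC content and 3′ untranslated regions (UTRs) were taken from GENCODE mouse transcripts, matched by symbol or synonym. Every sequence of 7 bases was scanned in the UTRs of 11405 tested genes with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. The model was tested on simulated data for siCYP1B1 against scrambled in vehicle, with 11835 genes of which 50 were changed at each size. It recovered 76% of changes of 0.25, 94% of 0.5, 98% of 1 and 100% of 2 on the log2 scale, with 10 false calls. The simulated noise was independent between genes, with 1 dispersion (0.00197) for all of them. In the real libraries 1 component held 24.6% of the variance left within groups, so these rates may not carry over.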

Results

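RNA sequencing profiles were compared between 6 groups of 3 libraries of mouse cells labelled as pulmonary microvascular endothelial cells. The design asked how E2 (estradiol) and 16aOHE act on these cells with scrambled siRNA or with siRNA against CYP1B1, a cytochrome P450 that metabolizes estradiol. 16aOHE is the usual short name of a 16-alpha-hydroxylated estrone, an estrogen metabolite with an added hydroxyl group and with a ketone in place of a hydroxyl group of estradiol. At the estimated depth 1 CPM stood for 14.1 reads in the shallowest library and for 38.5 reads in the deepest. The first principal component of the tested genes held 32.3% of the variance and the second 21.2%.

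Markers of more than 1 cell type were measured in every library. Of 26 listed endothelial markers, 19 were in the table, with a median level of 0.824 CPM. Pecam1 and Vwf, classical endothelial markers, averaged 0.0482 ± 0.0593 and 0.0306 ± 0.0589 CPM (SD, n = 18 libraries), whereas Cd34 averaged 107 ± 32.2 CPM and the VEGF receptor Flt1 70.0 ± 11.3 CPM. Of 15 listed epithelial and mesothelial markers, 13 were in the table, with a median level of 0.858 CPM. Among them, the mesothelial genes Msln, Upk3b and Wt1 averaged 1520 ± 130, 825 ± 245 and 256 ± 41.0 CPM. The collagen genes Col1a1 and Col3a1 averaged 1950 ± 269 and 2488 CPM. Of the 13 smooth muscle markers in the table, the actin-binding Cald1 was highest (965 CPM) and 4 reached 10 CPM. Acta2 averaged 20.5 ± 7.11 CPM and the contractile gene Myh11 0.0765 ± 0.0877 CPM. Of the leukocyte markers, Ptprc averaged 0.0313 ± 0.0462 CPM and Cd14 22.0 ± 1.01 CPM. Esr1, the gene of estrogen receptor alpha, averaged 14.9 ± 1.73 CPM, Esr2 0.121 ± 0.0859 CPM and Gper1 0.0520 ± 0.0492 CPM.

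**Figure D1:**
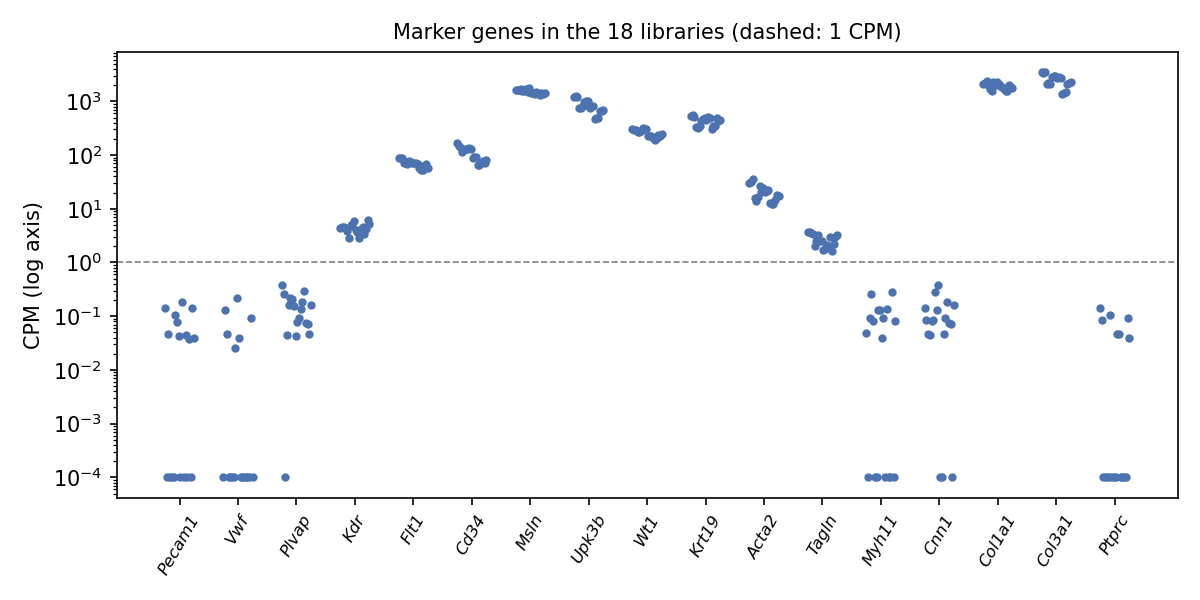
CPM of 17 marker genes on a log axis, with 1 point per library (18 libraries) and a dashed line at 1 CPM. Pecam1, Vwf and Plvap lay below 1 CPM in every library, and Msln, Upk3b and Wt1 above 100 CPM; points at 1e-04 are values listed at the offset.

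The targeted gene was examined first. Cyp1b1 (chromosome 17, 79706953 to 79715041, minus strand, mm10) was lower with siCYP1B1 in each arm, and by a small amount. It averaged 92.2 ± 3.58 CPM with scrambled siRNA and 81.5 ± 0.724 CPM with siCYP1B1 in vehicle (n = 3 each), and fell by 11.7%. It fell by 12.7% in E2 and by 15.2% in 16aOHE. The log2 differences were -0.18 (SE 0.0345, adjusted p = 0.000982), -0.19 (adjusted p = 0.000357) and -0.24 (adjusted p = 5.85e-05). Averaged over the arms, the difference was -0.20 (95% interval -0.24 to -0.16, adjusted p = 5.83e-08), and Cyp1b1 was lower in 9 of 9 siCYP1B1 libraries than in any scrambled library of the same arm. The exact permutation p within arms was 0.00025, the smallest that the 8000 rearrangements can give. Of the 2156 genes called lower in the averaged comparison, 932 (43.2%) fell by more than Cyp1b1. Both estrogens raised Cyp1b1 in scrambled cells, E2 by 27.5% (adjusted p = 2.41e-07) and 16aOHE by 15.3% (adjusted p = 0.00104).

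**Figure D2:**
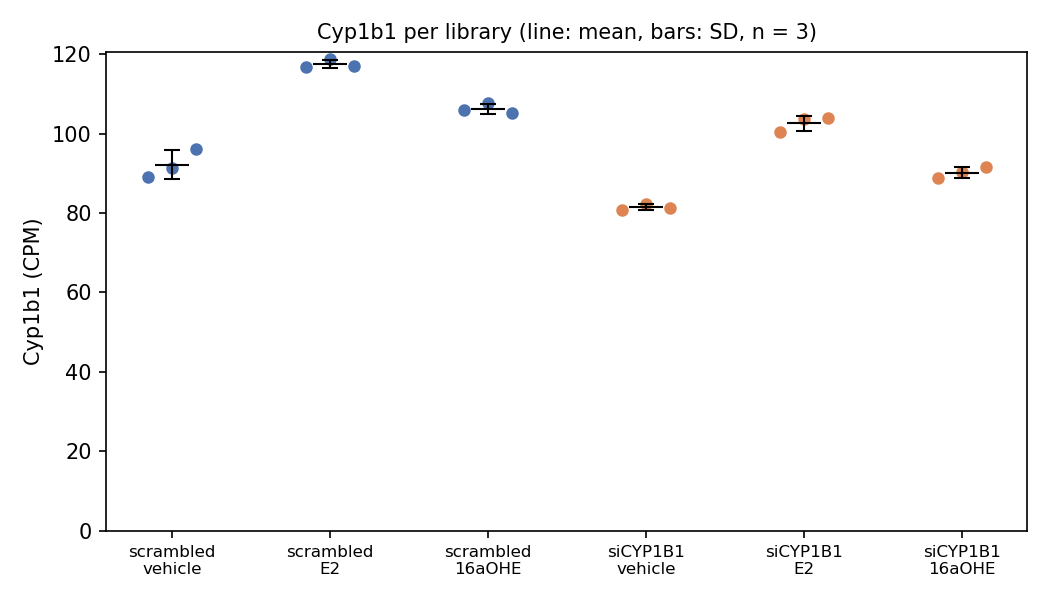
Cyp1b1 in CPM in the 6 groups, with 1 point per library, the mean as a line and the SD as bars (n = 3). The siCYP1B1 libraries lay below the scrambled libraries of the same arm, with means of 81.5 against 92.2 CPM in vehicle, 103 against 118 CPM in E2 and 90.1 against 106 CPM in 16aOHE.

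The first comparison asked what siCYP1B1 changed in vehicle. Part of the matrix genes and mesothelial markers on the fixed lists were lower, and part of the cell cycle genes were higher. The largest fall was in Angptl7, an angiopoietin-like secreted protein, from 84.1 ± 11.6 to 22.6 ± 0.355 CPM (n = 3, log2 -1.84, SE 0.117, adjusted p = 6.98e-10). Next came C4b of the complement system (-1.15; it shares sequence with C4a, which makes its level uncertain), the perforin-like Mpeg1 (-1.13), the imprinted gene Mest (-1.12) and the growth factor gene Gdf6 (-1.05). Adgrb2 (-0.93), the claudin Cldn15 (-0.93), the granzyme inhibitor Serpinb9 (-0.90), the interferon-induced GTPase Iigp1 (-0.89) and the matricellular gene Ctgf (-0.88) completed the 10 named decreases. The named increases were the deubiquitinase gene Usp43 (1.11), the stanniocalcin Stc2 (1.01), Ly6d (0.99), Serpinb10 (0.87), the protease Htra3 (0.81), the clock repressor Bhlhe41 (0.79), Prl2c2 (0.79) and Chrna6 (0.79), together with Rn45s (0.84) and Rps16 (0.80). Prl2c2, Rn45s and Rps16 have near-identical copies and are uncertain, and the call of Rn45s was lost under several settings. In all, 2437 of 11835 genes passed (1358 higher and 1079 lower, or 55.7% higher against 40.7% with median-of-ratios factors), of which 8 changed at least 2-fold.

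The groups of genes that differed between siCYP1B1 and scrambled siRNA in vehicle could be counted from the fixed lists. The samples hold no group without siRNA, so that an effect of the scrambled siRNA cannot be told apart from an effect of siCYP1B1. Of 28 interferon-response genes, 15 were lower (17 lower adjusted over the list alone, camera adjusted p = 3.36e-11), among them the chemokine Cxcl10 (-0.63) and the nucleic acid sensor Zbp1 (-0.51). The camera call was lost otherwise (adjusted p = 0.0824 with an estimated correlation). Of 25 TGF-beta and matrix genes, 13 were lower and 3 higher (16 and 3 adjusted over the list alone, adjusted p = 8.24e-09), led by Loxl1 (-0.84), Col8a1 (-0.45) and Timp3 (-0.44). Of 22 cholesterol synthesis genes, 8 were lower (10 adjusted over the list alone, adjusted p = 1.56e-05), with Idi1 at -0.24, but the list call was lost with adjusted p = 0.233 with an estimated correlation. Of 16 NF-kB inflammatory genes, 4 were lower and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.0155, and adjusted p = 0.0824 with an estimated correlation), with Csf1 at -0.31.

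Part of the markers of 4 cell types were lower in the same comparison. Of 6 tested epithelial and mesothelial markers, 4 were lower (5 adjusted over the list alone, adjusted p = 4.88e-07), with Upk3b falling from 1224 ± 15.1 to 797 ± 36.4 CPM (n = 3, -0.62) and Wt1 at -0.40. Of 7 fibroblast and pericyte markers 3 were lower (3 adjusted over the list alone, adjusted p = 7.33e-05), with Dcn at -0.54 and Col3a1 at -0.36. Of 9 endothelial markers 4 were lower (4 adjusted over the list alone, adjusted p = 0.000365), with Cd34 at -0.73 and Flt1 at -0.34. Of 7 smooth muscle markers 2 were lower, Acta2 (-0.57) and Tagln (-0.69; 2 adjusted over the list alone, adjusted p = 0.0287). The smooth muscle call was lost with quantile normalization, and was lost with adjusted p = 0.0824 with an estimated correlation.

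Of the groups that were higher, 16 of 32 cell cycle genes rose and none fell (20 adjusted over the list alone, adjusted p = 3.55e-08), by small amounts such as 0.26 for the cyclin Ccne1 and 0.23 for Rrm2. Of 15 oxidative phosphorylation genes 13 rose (14 adjusted over the list alone, adjusted p = 1.2e-08, and adjusted p = 0.0824 with an estimated correlation), including Cox5a (0.28) and Atp5b (0.27). Of 24 glycolysis and hypoxia genes 10 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 0.000183), including Pfkp (0.35). Of 20 NRF2 targets 10 rose (10 adjusted over the list alone, adjusted p = 1.99e-05, and adjusted p = 0.0713 with an estimated correlation), including the ferritin genes Ftl1 (0.45) and Fth1 (0.37) and the heme oxygenase Hmox1 (0.27). Of 15 clock genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0189, and adjusted p = 0.314 with an estimated correlation), with Dbp at 0.68 and Nr1d1 at 0.56. Of 20 p53 targets 5 rose (6 adjusted over the list alone, adjusted p = 0.0287, and adjusted p = 0.264 with an estimated correlation), including Sesn2 (0.33). Of 20 ribosomal protein genes, listed as a sign of RNA quality, 12 were higher (15 adjusted over the list alone, adjusted p = 4.48e-06, and adjusted p = 0.0824 with an estimated correlation). Several of them stood near 1.5 CPM (Rpl3 1.48, Rps18 1.49) beside 1020 CPM for Rpl4, and reads shared with processed copies make them uncertain.

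Lists without a call in this comparison were estrogen receptor targets (3 higher and 3 lower of 20, 5 and 3 adjusted over the list alone, adjusted p = 0.665), estrogen metabolism enzymes (2 and 3 of 12, the same adjusted over the list alone, 0.665), aryl hydrocarbon receptor targets (2 and 2 of 9, the same adjusted over the list alone, 0.296), the BMP pathway (0 and 4 of 14, 1 and 4 adjusted over the list alone, 0.0637), fatty acid metabolism (4 and 4 of 19, 5 and 4 adjusted over the list alone, 0.844), the unfolded protein response (4 and 3 of 20, the same adjusted over the list alone, 0.844), immediate early genes (1 and 1 of 14, the same adjusted over the list alone, 0.531) and nuclear-retained RNAs (0 of 3; 0.624). The last list was not called in any contrast. Esr1 did not pass (log2 -0.07, adjusted p = 0.633), and neither did the 2 tested leukocyte markers Cd14 (0.00, adjusted p = 0.97) and Cd68 (-0.10, adjusted p = 0.566).

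The siRNA comparison was then made in the estrogen arms. Angptl7 was lower in E2 (log2 -1.92) and in 16aOHE (-1.61), as were Mpeg1 (-1.27 and -1.03) and Igfbp5, an IGF-binding protein gene (-1.15 and -1.26), while Usp43 was higher (1.04 and 0.90). In E2, 2506 genes passed (1346 higher and 1160 lower, 53.7% higher against 40.6% with median-of-ratios factors), and in 16aOHE 2331 passed (1229 and 1102, 52.7% higher against 45.3%). The count in 16aOHE fell to 1538 when only those 2 groups were fitted, and also to 1538 without the library scrambled 16aOHE 1. Across genes, which are not independent replicates, the log2 changes correlated between arms with r from 0.698 to 0.768, in comparisons that share no library. Averaged over the arms, 5296 genes passed (3140 higher and 2156 lower, 59.3% higher against 49.4% with median-of-ratios factors), including 29 of 32 cell cycle genes higher (29 adjusted over the list alone). Epithelial and mesothelial markers were lower in 4 of 6 cases (5 adjusted over the list alone) and fibroblast and pericyte markers in 5 of 7 (7 adjusted over the list alone), each with adjusted p = 0.00578 with an estimated correlation. Of 28 interferon-response genes 21 were lower and 2 higher (23 and 2 adjusted over the list alone, adjusted p = 1.11e-11, and adjusted p = 0.117 with an estimated correlation). TGF-beta and matrix genes were lower in 18 of 25 cases and higher in 3 (the same adjusted over the list alone, camera adjusted p = 1.1e-07). Endothelial markers were lower in 4 of 9 cases (camera adjusted p = 0.00122). Glycolysis and hypoxia genes were higher in 15 of 24 cases and lower in 1 (camera adjusted p = 0.000687). These 3 list calls were lost with an estimated correlation (adjusted p = 0.0569 each). All 15 oxidative phosphorylation genes were higher (15 adjusted over the list alone, adjusted p = 7.88e-08, and adjusted p = 0.12 with an estimated correlation). So were 13 of 20 ribosomal protein genes of the RNA quality list (13 adjusted over the list alone, adjusted p = 0.000687, and adjusted p = 0.177 with an estimated correlation). A sequence of 7 bases, AAAGTCA, lay in the 3′ UTR of 26.7% of the 2106 genes called lower in the averaged comparison and of 9.0% of the 3065 called higher whose UTR was searched. On the estrogen receptor list, Esr1 fell by 0.16 (adjusted p = 0.0231), a call lost without scrambled vehicle 2 or scrambled E2 2. Esrra, listed with it but the gene of the estrogen-related receptor alpha and not of an estrogen receptor, rose by 0.30 (adjusted p = 1.5e-07).

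**Figure D3:**
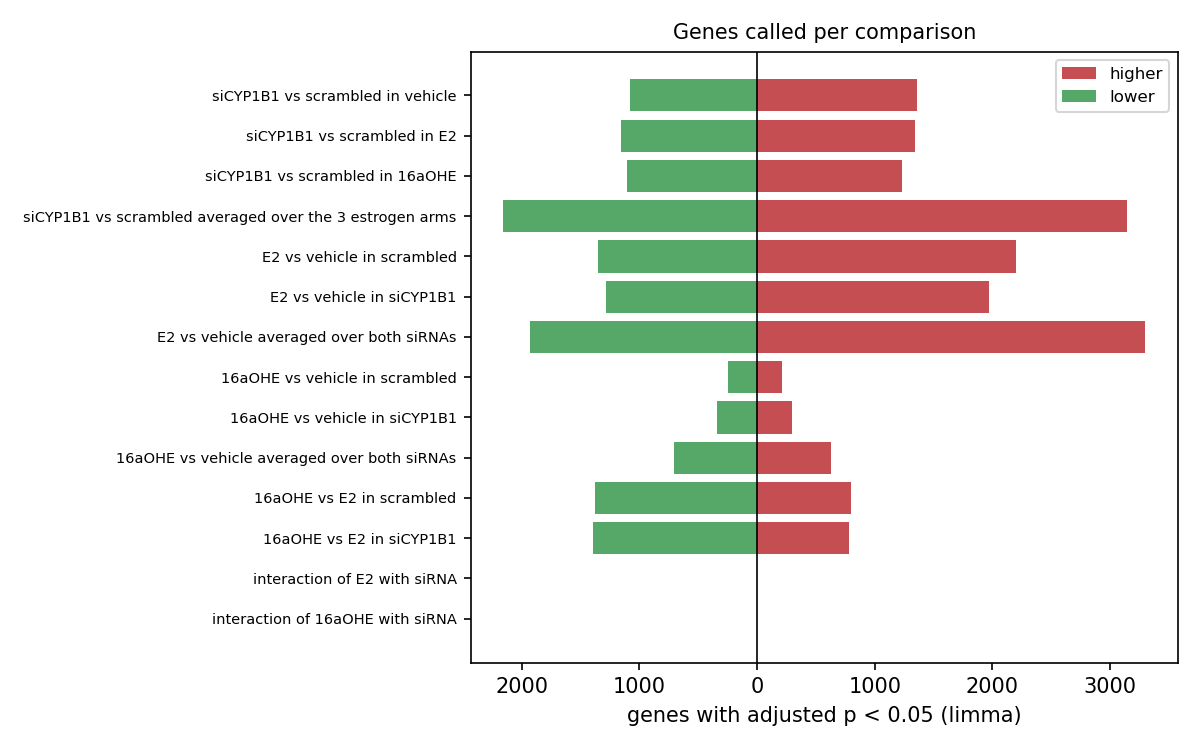
Number of genes called higher (right) or lower (left) in each of the 14 contrasts (limma, adjusted p under 0.05, of 11835 genes tested). In scrambled cells 454 genes were called for 16aOHE and 3548 for E2 against vehicle, the averaged comparisons reached 5296 for siCYP1B1 and 5228 for E2, and both interactions had 0.

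E2 was compared with vehicle in scrambled cells. It raised part of the NRF2 targets and of the hypoxia genes on the fixed lists, and lowered part of the mesothelial, endothelial and fibroblast markers and of the cell cycle genes. Mt2 (chromosome 8, 94172618 to 94173567, mm10), a metal-binding metallothionein, rose from 10.9 ± 0.242 to 45.6 ± 3.39 CPM (n = 3, log2 1.97, SE 0.0792, adjusted p = 2.23e-13), and Mt1 rose by 1.34. The other named increases were Stc2 (5.61 ± 0.222 to 17.7 ± 0.818 CPM, n = 3), the glycosphingolipid enzyme A4galt (1.40), the transcription factor Klf15 (1.17), Sprr1a (1.06), the angiopoietin Angpt2 (1.02), Hdac11 (0.99), the mitochondrial folate enzyme Aldh1l2 (0.98) and Tacc1 (0.96). The keratin gene Krt18 fell from 8.17 ± 0.0641 to 1.35 ± 0.352 CPM (n = 3, -1.98, adjusted p = 1.17e-09), followed by Plxnb3 (-1.82), Krt14 (-1.58), the endothelial matrix gene Mmrn2 (-1.46), Col2a1 (-1.42), S100a3 (-1.34), Mrgprf (-1.34), Mest (-1.34), Rnf112 (-1.33) and Fam84a (-1.26). In all, 3548 genes passed, 2199 higher and 1349 lower. The share higher was 62.0% as deposited, 51.0% with quantile normalization and 45.9% with median-of-ratios factors. Changes of at least 2-fold numbered 41, of which 34 were falls.

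NRF2 targets, the genes of the oxidative stress response, rose with E2 in 12 of 20 cases (15 adjusted over the list alone, adjusted p = 2.78e-07), including Hmox1 (0.58), the quinone reductase Nqo1 (155 ± 6.29 to 229 ± 14.1 CPM, n = 3, log2 0.56) and Fth1 (0.46). Of 24 glycolysis and hypoxia genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 0.000132), including Bnip3 (0.88), the pyruvate dehydrogenase kinase Pdk1 (0.82) and the glucose transporter Slc2a1 (0.45). Of 20 genes of the unfolded protein and amino acid stress response 9 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 0.00955, and adjusted p = 0.238 with an estimated correlation), and the risers included Trib3 (0.83), Chac1 (0.79) and the asparagine synthetase Asns (0.52). Of 9 aryl hydrocarbon receptor targets 5 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.0247, and adjusted p = 0.0618 with an estimated correlation), of which Cyp1b1 and Nqo1 are also estrogen metabolism genes. Of 12 estrogen metabolism enzymes 6 rose (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.0308, and adjusted p = 0.261 with an estimated correlation). Of 15 clock genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 0.0247, and adjusted p = 0.372 with an estimated correlation), with Dbp at 0.81.

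Part of the markers of 4 cell types were lower with E2. Epithelial and mesothelial markers fell in 5 of 6 cases (5 adjusted over the list alone, adjusted p = 2.53e-07), with Upk3b at -0.66 and Cdh1 at -0.92. Endothelial markers fell in 6 of 9 cases (6 adjusted over the list alone, adjusted p = 5.58e-05), with Esam at -0.79. Fibroblast and pericyte markers fell in 4 of 7 cases and rose in 1 (4 and 2 adjusted over the list alone, adjusted p = 0.0022), with Col3a1 falling from 3510 ± 72.6 to 2116 ± 44.6 CPM (n = 3, -0.73). Smooth muscle markers fell in 3 of 7 cases (3 adjusted over the list alone, adjusted p = 0.00955), with Acta2 at -1.03. Of 32 cell cycle genes 19 fell and 1 rose (21 and 2 adjusted over the list alone, adjusted p = 5.56e-08), with the mitotic kinase Plk1 at -0.28. Of 25 TGF-beta and matrix genes 12 fell and 2 rose (14 and 2 adjusted over the list alone, adjusted p = 7.25e-05, and adjusted p = 0.0785 with an estimated correlation). Fatty acid genes fell in 5 of 19 cases and rose in 2 (5 and 2 adjusted over the list alone, adjusted p = 0.0104), with Angptl4 at -0.83.

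Further lists were called lower with E2 by the preset correlation and not by the estimated one. Cholesterol synthesis genes fell in 7 of 22 cases (7 adjusted over the list alone, adjusted p = 0.00051, and adjusted p = 0.334 with an estimated correlation). NF-kB genes fell in 7 of 16 cases and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.00955, and adjusted p = 0.0618 with an estimated correlation). Immediate early genes fell in 5 of 14 cases (5 adjusted over the list alone, adjusted p = 0.00955, and adjusted p = 0.261 with an estimated correlation). Estrogen receptor targets moved both ways, 6 higher and 5 lower of 20 (6 and 6 adjusted over the list alone, adjusted p = 0.797), with Stc2 higher and Igfbp4 lower (-0.36). Interferon-response genes were not called as a list either (8 higher and 1 lower of 28, 10 and 1 adjusted over the list alone, adjusted p = 0.353), although Rsad2 rose by 0.61. In siCYP1B1 cells E2 called 3254 genes (1971 higher and 1283 lower, 60.6% higher against 44.7% with median-of-ratios factors), and the log2 changes correlated with those in scrambled cells across genes with r = 0.836, with no shared library. Averaged over both siRNAs 5228 genes passed (3300 higher and 1928 lower, 63.1% higher against 52.3% with quantile normalization and 47.7% with median-of-ratios factors).

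**Figure D4:**
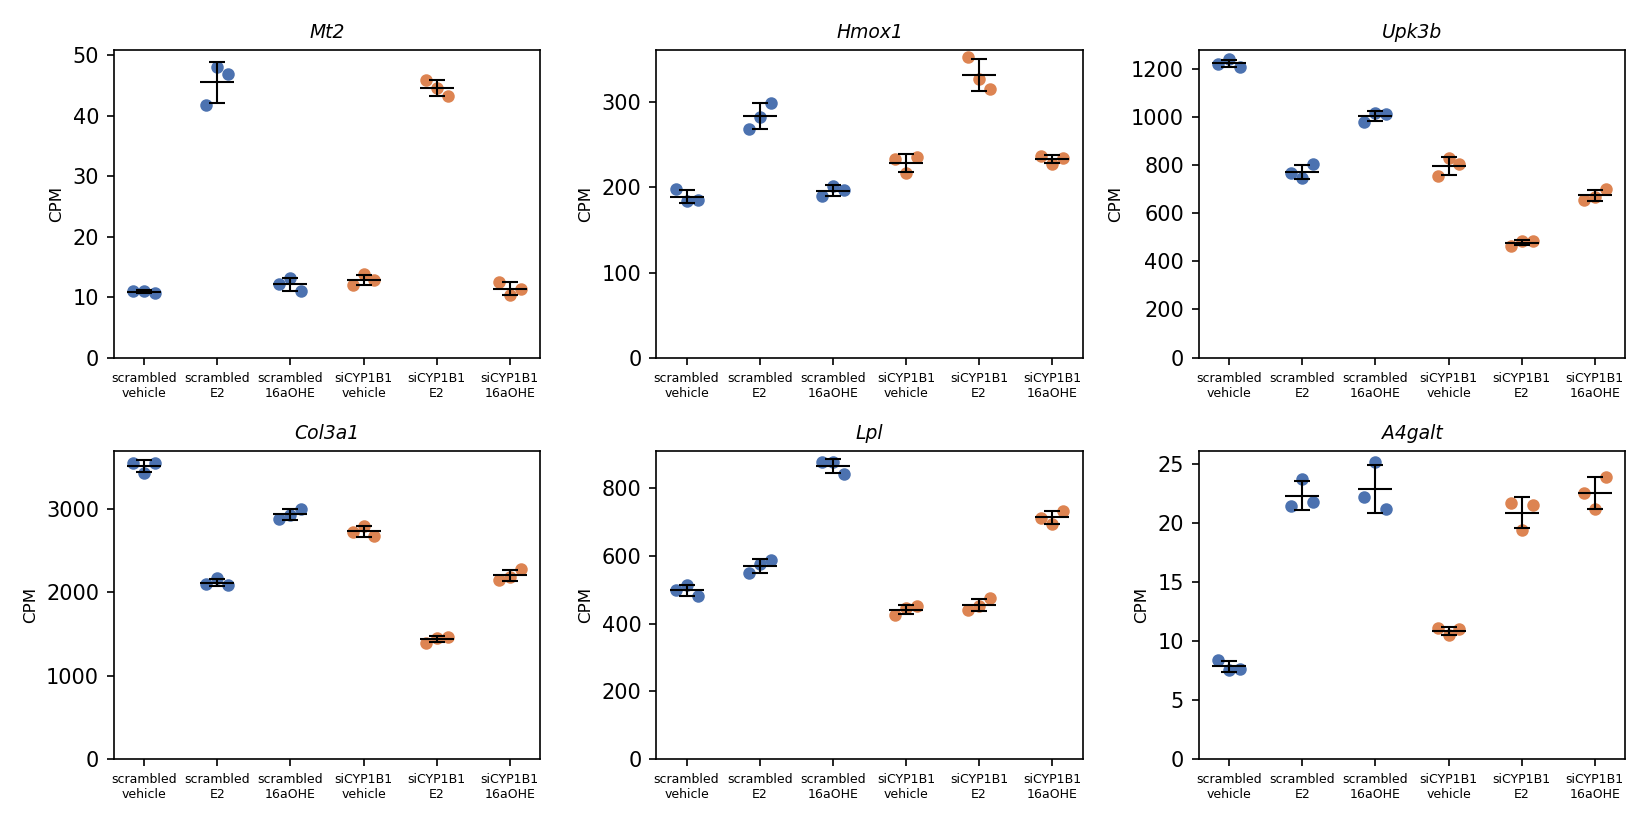
CPM of Mt2, Hmox1, Upk3b, Col3a1, Lpl and A4galt in the 6 groups, with 1 point per library, the mean as a line and the SD as bars (n = 3, blue scrambled, orange siCYP1B1). In scrambled cells Mt2 averaged 45.6 CPM with E2 and 12.1 CPM with 16aOHE against 10.9 CPM with vehicle, whereas A4galt averaged 22.3 and 22.9 CPM against 7.84 CPM.

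16aOHE was compared with vehicle in scrambled cells. It raised A4galt (chromosome 15, 83226722 to 83251774, mm10) from 7.84 ± 0.442 to 22.9 ± 2.07 CPM (n = 3, log2 1.43, SE 0.0758, adjusted p = 8.25e-11) and the lipoprotein lipase gene Lpl from 498 ± 15.2 to 866 ± 20.4 CPM (n = 3, 0.80, adjusted p = 1.05e-11). The other named increases were the stem cell receptor gene Lgr6 (1.08), Sprr1a (1.06), Stc2 (1.05), the interleukin receptor gene Il4ra (1.01), Angpt2 (0.97), Tacc1 (0.96), Adamts3 (0.87) and Serpinb2 (0.82). The named decreases were Fam84a (-1.06), the cadherin Cdh1 (-0.81), Sncg (-0.78), Lrrc4 (-0.75), C9 (-0.74), Scara5 (-0.74), the Notch ligand Jag1 (-0.71), Ptn (-0.71), Krt14 (-0.71) and Mrgprf (-0.71). Angpt2 and C9 lost their calls when any of several single libraries was left out, and Scara5 and Mrgprf without the first-listed library of every group. In all, 454 genes passed (208 higher and 246 lower), 6 of them by at least 2-fold, and leaving out any 1 of their libraries gave 248 to 306 (282 and 284 without scrambled vehicle 1 or 2, 248 and 285 without scrambled 16aOHE 1 or 3). The count was 264 without the first-listed library of every group, 652 with that library as a block and 711 with the residual component as a covariate (356 higher and 355 lower).

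Of 22 cholesterol synthesis genes 5 were called lower with 16aOHE (13 adjusted over the list alone, adjusted p = 6.86e-11, and adjusted p = 0.11 with an estimated correlation), including Hmgcs1 (-0.20) and Msmo1 (-0.21). Of 20 genes of the unfolded protein response 2 were called higher (7 adjusted over the list alone, adjusted p = 3.26e-05, and adjusted p = 0.0685 with an estimated correlation). Epithelial and mesothelial markers were called lower in 3 of 6 cases (4 adjusted over the list alone, adjusted p = 0.000907, and adjusted p = 0.051 with an estimated correlation), with Upk3b at -0.29. Cell cycle genes had 1 of 32 called lower (1 adjusted over the list alone, adjusted p = 0.000699, and adjusted p = 0.0685 with an estimated correlation). Endothelial markers had 2 of 9 lower (4 adjusted over the list alone, adjusted p = 0.00195), with Flt1 at -0.26, and fibroblast markers 4 of 7 lower (4 adjusted over the list alone, adjusted p = 0.00361), with Col3a1 at -0.26. Both marker lists had an adjusted p = 0.0685 with an estimated correlation, and none of the list calls in this comparison held under it. Of 16 NF-kB genes 4 fell and 1 rose (5 and 2 adjusted over the list alone, adjusted p = 0.0331, and adjusted p = 0.133 with an estimated correlation), with Ccl2 falling by 0.50 and Tnfaip3, a feedback inhibitor, as the riser (0.54). Of 14 immediate early genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.0163, and adjusted p = 0.312 with an estimated correlation), with Ier3 at 0.36. NRF2 targets had 2 of 20 higher and 1 lower (2 and 1 adjusted over the list alone, adjusted p = 0.0125, and adjusted p = 0.244 with an estimated correlation), and estrogen receptor targets 3 higher and 1 lower of 20 (3 and 3 adjusted over the list alone, adjusted p = 0.138).

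In siCYP1B1 cells 16aOHE called 639 genes (300 higher and 339 lower), with A4galt at 0.99, Lgr6 at 0.96, the protocadherin gene Pcdh10 at 0.83, Scara5 at -1.19 and Fam84a at -0.98. That count was 365 when only the 2 groups were fitted and 306 to 755 without any 1 library (384 and 316 without siCYP1B1 vehicle 2 or 3, 306 without siCYP1B1 16aOHE 2), 1067 with the first-listed libraries as a block and 1155 with the residual component as a covariate. Averaged over both siRNAs 1338 genes passed (631 higher and 707 lower), including 15 of 22 cholesterol synthesis genes lower (16 adjusted over the list alone, adjusted p = 6.76e-10, and adjusted p = 0.135 with an estimated correlation). In the averaged comparison the falls in cell cycle genes (7 of 32 lower and 1 higher, 11 and 1 adjusted over the list alone), in epithelial and mesothelial markers (4 of 6, 4 lower and 1 higher adjusted over the list alone) and in fibroblast markers (4 of 7, 4 adjusted over the list alone) each reached adjusted p = 0.0477 with an estimated correlation. Endothelial markers had 4 of 9 lower (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0046, and adjusted p = 0.0917 with an estimated correlation). Ribosomal protein genes, the RNA quality list, had 0 of 20 called (0 adjusted over the list alone) and were called lower as a list (adjusted p = 0.00177, and adjusted p = 0.273 with an estimated correlation). In siCYP1B1 cells alone 3 of those 20 were lower (9 adjusted over the list alone, adjusted p = 6.7e-06, and adjusted p = 0.22 with an estimated correlation).

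The 2 estrogens were compared directly at the matched dose of 1 uM and time of 24 hours. In scrambled cells part of the NRF2 targets and hypoxia genes were lower with 16aOHE than with E2, and part of the matrix genes, mesothelial markers and fatty acid genes were higher. Mt2 was at 12.1 ± 1.10 CPM with 16aOHE and 45.6 ± 3.39 CPM with E2 (n = 3, log2 difference -1.83, SE 0.0792, adjusted p = 2.89e-12), Mt1 differed by -1.39, and the named genes lower with 16aOHE further held Klf15 (-0.94), Fgfr1 (-0.89) and Bnip3 (-0.77). Those higher with 16aOHE were Krt18 (1.45, 95% interval 1.17 to 1.73), Plxnb3 (1.22), the endothelin gene Edn1 (1.14), Rnf112 (0.90) and Krt14 (0.88). In all, 2180 genes differed, 802 higher and 1378 lower with 16aOHE. The share higher was 36.8% as deposited, 49.4% with quantile normalization and 55.1% with median-of-ratios factors. In siCYP1B1 cells 2171 genes differed (780 higher and 1391 lower, 35.9% higher as deposited against 52.0% and 59.2% under those scalings), with Mt2 at -1.88, Pappa at 1.27 and Edn2 at 1.12, and the count was 1446 without siCYP1B1 16aOHE 2.

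Lists that separated the 2 estrogens in scrambled cells, with both the preset and an estimated correlation, were NRF2 targets (11 of 20 lower with 16aOHE, 12 adjusted over the list alone, adjusted p = 4.67e-06), and glycolysis and hypoxia (10 of 24 lower, 11 adjusted over the list alone, 8.03e-05). Also separated in this way were TGF-beta and matrix (14 of 25 higher, 15 adjusted over the list alone, 2.39e-09), epithelial and mesothelial markers (4 of 6 higher, 4 adjusted over the list alone, 8.72e-07) and fatty acid metabolism (7 of 19 higher and 2 lower, 7 and 2 adjusted over the list alone, 0.0017). The remaining lists were cell cycle (6 of 32 higher, 6 adjusted over the list alone, 1.26e-05), endothelial markers (4 of 9 higher, 5 adjusted over the list alone, 0.00197), fibroblast and pericyte markers (4 of 7 higher and 1 lower, 4 and 2 adjusted over the list alone, 0.00711) and immediate early genes (5 of 14 higher, 7 adjusted over the list alone, 8.72e-07). In siCYP1B1 cells 2 of these lists gave no such call. Immediate early genes had 2 of 14 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.321). Cell cycle genes had 4 of 32 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.00561, and adjusted p = 0.129 with an estimated correlation). Examples in scrambled cells were Hmox1 (-0.53), Pdk1 (-0.74), Ctgf (0.72), Upk3b (0.38), Lpl (0.60), Plk1 (0.22) and Jun (0.40). The estrogens were close for A4galt, with 22.3 ± 1.26 CPM in E2 and 22.9 ± 2.07 CPM in 16aOHE, and for Tacc1, with 214 ± 8.37 and 214 ± 10.7 CPM (n = 3 each). Their log2 differences were 0.03 (SE 0.0758, adjusted p = 0.817) and 0.00 (SE 0.0520, adjusted p = 0.97). Cyp1b1 itself was lower with 16aOHE than with E2 in scrambled cells (log2 -0.14, 95% interval -0.22 to -0.07, adjusted p = 0.00564).

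The E2 and 16aOHE responses were also compared over all genes. In scrambled cells the log2 changes correlated across genes with r = 0.616 and Spearman's rho = 0.539. Simulated unchanged groups with shared controls had a median r of 0.509 (central 95% of 100 draws 0.06 to 0.815). These draws took residuals from all 18 libraries regardless of group. Unlike the real groups, they did not hold 1 first-listed library each, which may widen the spread of r. The draws therefore cannot decide whether r exceeds that of unchanged groups. The covariance was 0.0172, beside a median of 0.00444 in those draws. Genes called higher in both numbered 158, beside 38.6 for independent lists, and genes lower in both 206, beside 28.0, with 9 called in opposite directions. Comparisons sharing no library gave r = 0.415 for E2 in scrambled against 16aOHE in siCYP1B1 cells, and r = 0.493 for E2 in siCYP1B1 against 16aOHE in scrambled cells. For simulated unchanged groups sharing no library, drawn in the same way, the central 95% of r ran from -0.505 to 0.479. The first of these values lies within those limits, and the second just above them. The 3 vehicle libraries cannot be divided into sets of at least 2, and part of the excess within an siRNA may come from sharing them. An excess over independent lists remained in the 2 comparisons sharing no library. In the order above, genes higher in both numbered 167 and 133, beside 55.7 and 34.6 for independent lists. Genes lower in both numbered 208 and 202, beside 38.6 and 26.7, and 24 and 7 were called in opposite directions, beside 97.2 and 63.5. Independent lists are a low benchmark, since an siRNA and an estrogen comparison sharing no library could exceed it too. For siCYP1B1 in E2 against 16aOHE in scrambled cells, 98 genes were lower in both beside 24.1. In that pair 23 were higher in both beside 23.7, and 88 were opposite beside 48.4.

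The last comparison asked whether siCYP1B1 altered the response to either estrogen. No gene passed for E2 or for 16aOHE in limma (470 and 596 genes at an unadjusted p under 0.05, beside 592 expected by chance). limma-voom on estimated reads also called 0 in both. For 16aOHE the count was not 0 under every setting. It was 2 with robust eBayes and 12 when only the 4 groups concerned were fitted. It was 10 with the residual component as a covariate, 7 with the first-listed libraries as a block, 2 without the first-listed library of every group and 1 without siCYP1B1 vehicle 3. Psmb5, Rps16 and Rpl15 passed with the block and when only those groups were fitted. The genes nearest to passing with E2 were Stc2 (interaction log2 -0.71, adjusted p = 0.386), A4galt, which E2 raised from 7.84 ± 0.442 to 22.3 ± 1.26 CPM in scrambled and from 10.8 ± 0.332 to 20.8 ± 1.30 CPM in siCYP1B1 cells (n = 3 each, interaction -0.52, adjusted p = 0.389), and Tacc1 (-0.34, adjusted p = 0.389). In the other direction were Zdhhc2 (0.37, adjusted p = 0.389), Shisa8 (0.67, adjusted p = 0.998) and Junb (0.21, adjusted p = 0.998). With 16aOHE they were Psmb5 (-0.55, adjusted p = 0.0656), Rps16 (-1.31, adjusted p = 0.0801, uncertain because of copies) and Rpl15 (-0.37, adjusted p = 0.133), and in the other direction Atp5g1 (0.62, adjusted p = 0.382), Chmp4c (0.49, adjusted p = 0.406) and Fzd8 (0.42, adjusted p = 0.406). The median 95% interval of an interaction, not adjusted for the number of genes, reached 0.188 to either side on the log2 scale. Passing after adjustment over all genes took larger differences, and interactions well above 0.188 are among those named as not passing. The absence of calls thus does not exclude differences of that size between the siRNAs.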

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

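In this part, the counts over other splits of the libraries were chosen only after the result was seen, and the list tests were not. Several gene lists differed between siCYP1B1 and scrambled cells in their response to an estrogen, each by a camera test of the interaction with the preset correlation, while no single member passed over all genes. With E2, the response of cholesterol synthesis genes was lower in siCYP1B1 cells (median interaction log2 -0.09 over 22 genes, adjusted p = 2.22e-06, 1 lower adjusted over the list alone, and adjusted p = 0.351 with an estimated correlation). NRF2 targets differed in the same direction with E2 (median -0.09 over 20 genes, adjusted p = 0.0017, 0 adjusted over the list alone, and adjusted p = 0.312 with an estimated correlation). Fibroblast and pericyte markers had a median of -0.19 over 7 genes with E2 (adjusted p = 0.0122, 1 lower adjusted over the list alone, and adjusted p = 0.197 with an estimated correlation).

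With 16aOHE, immediate early genes had a median interaction log2 of -0.24 over 14 genes (adjusted p = 0.000154, 4 lower adjusted over the list alone, and adjusted p = 0.334 with an estimated correlation). Their median change was 0.09 in scrambled and -0.06 in siCYP1B1 cells. Egr1 (-0.64) passed singly with the first-listed library of each group as a block or left out, or with the residual component as a covariate. NRF2 targets had a median of -0.10 over 20 genes (adjusted p = 0.00104, 0 adjusted over the list alone, and adjusted p = 0.334 with an estimated correlation). Ribosomal protein genes had a median of -0.12 over 20 genes (adjusted p = 0.000112, 4 lower adjusted over the list alone, and adjusted p = 0.334 with an estimated correlation), and they are uncertain because of processed copies.

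Single genes called for the interactions numbered 0 for each estrogen by limma (470 and 596 at an unadjusted p under 0.05). A count of 0 is reached by every split by construction (100 of 100 for E2 and 100 of 100 for 16aOHE), so that the splits say nothing about the interactions. The highest counts in other splits were 1118 for E2 and 4075 for 16aOHE. Those splits exchanged siRNA labels within an arm, by which the siRNA effect itself enters as an apparent interaction, a structure of the samples and not a response to an estrogen.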

How the results depend on the processing

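The fits by limma-voom on estimated reads, with the residual component as a covariate, with the first-listed library of each group as a block, and without the first-listed library of every group were chosen only after the result was seen. No named gene that was called in the reported fit or in the alternative turned its direction under any alternative run. The direction of values called in neither was not checked. No gene was called in opposite directions in the comparisons of groups. The side with more called genes did turn. With median-of-ratios factors fewer than 50% were higher for siCYP1B1 in each arm and averaged and for E2 in each siRNA and averaged, and more than 50% for 16aOHE against E2 in each siRNA. Quantile normalization turned that side for siCYP1B1 in each arm and for 16aOHE against E2 in siCYP1B1 cells, and fits of fewer libraries or with the covariate turned it for some comparisons near 50%. The numbers of genes called stayed within 1.5 times the reported count under both pseudocounts, both filters, both scalings and limma-voom for all 14 contrasts. They did so under every alternative run for siCYP1B1 in vehicle, in E2 and averaged, for E2 against vehicle and for 16aOHE against E2 in scrambled cells.

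When only the groups compared were fitted, 1538 genes were called for siCYP1B1 in 16aOHE, 365 for 16aOHE in siCYP1B1 cells and 12 for the 16aOHE interaction. With the residual component as a covariate the counts were 711 for 16aOHE in scrambled cells, 1155 in siCYP1B1 cells and 10 for the 16aOHE interaction. With the first-listed library of each group as a block they were 1067 for 16aOHE in siCYP1B1 cells and 7 for the 16aOHE interaction, and calls of 17 named gene values were gained and none lost. The component was taken from the residuals of the same fit, so that counts with it are raised by construction. Without the first-listed library of every group they were 264 for 16aOHE in scrambled cells and 2 for the 16aOHE interaction, and robust eBayes gave 2 for that interaction. The cause was not tested.

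Leaving out 1 library at a time gave 1538 to 2170 genes for siCYP1B1 in 16aOHE (1538 without scrambled 16aOHE 1, equal by coincidence to the count above). It gave 248 to 306 for 16aOHE in scrambled cells (282 without scrambled vehicle 1, 284 without scrambled vehicle 2, 248 without scrambled 16aOHE 1, 285 without scrambled 16aOHE 3). In siCYP1B1 cells it gave 306 to 755 (384 without siCYP1B1 vehicle 2, 316 without siCYP1B1 vehicle 3, 306 without siCYP1B1 16aOHE 2). For 16aOHE against E2 in siCYP1B1 cells it gave 1446 to 2229 (1446 without siCYP1B1 16aOHE 2), and for the 16aOHE interaction 0 to 1 (1 without siCYP1B1 vehicle 3).

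Of 156 list calls, 55 held with an estimated correlation, 142 with a mean of at least 5 CPM, 146 with no filter, 151 with quantile normalization and all 156 with a pseudocount of 0.25. Calls of named genes were lost in 562 of the fits that left out 1 library and gained in 24, against 9512 that stayed on the same side. They were lost for 73 values without the first-listed library of every group, 41 when only the groups compared were fitted, 32 with no filter, 28 with median-of-ratios factors, 20 with quantile normalization and at most 14 under any other setting.

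No paired analysis was possible because the labels give no replicate numbers shared between groups, libraries were numbered here by order only, and the block above rests on that order. The planned tests that need whole counts were not run, because not all values are whole. With 1 CPM standing for 14.1 reads in the shallowest library, changes of genes near 1 CPM are poorly measured.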

Other observations

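All comparisons of the size of the 2 estrogen responses, the tests of mislabelling and of cell identity, the size of the site effect, and the counts over other splits were chosen only after the result was seen. For 60 genes higher and 42 lower with 16aOHE averaged over both siRNAs, 16aOHE also differed from E2 in that direction in each siRNA, and for part of them the E2 change had the opposite sign. The lipase gene Lpl had averaged log2 changes of 0.75 with 16aOHE and 0.12 with E2, and the protocadherin gene Pcdh10 of 0.81 and 0.32. The NF-kB feedback gene Tnfaip3 had 0.46 and 0.04, and Lrp2, an endocytic receptor gene, 0.59 and 0.16. The matricellular genes Thbs1 (0.31 and -0.14), Cyr61 (0.36 and -0.11) and Ctgf (0.27 and -0.38), and the transcription factor gene Creb5 (0.40 and -0.27), had opposite signs with the 2 estrogens, and for Ctgf the change with E2 was the larger in size.

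The size of the 2 responses was compared over genes chosen in the other siRNA, a choice that favours the estrogen used for it. Ranges without any 1 library kept the chosen genes fixed, and so leave out the spread of that choice. For genes chosen in the other siRNA, only libraries of the siRNA measured were left out. Over 3254 genes chosen by E2 in siCYP1B1 cells and measured in scrambled cells, the mean change with 16aOHE was 0.332 times that with E2 (0.326 to 0.339 without any 1 library), and 79% of the genes moved in the same direction. Over 3548 genes chosen in scrambled cells and measured in siCYP1B1 cells it was 0.296 times (0.285 to 0.312), and 71.7% moved in the same direction. Over genes chosen by 16aOHE the ratio was 0.774 in scrambled cells (639 genes, 0.745 to 0.817 without any 1 library) and 0.749 in siCYP1B1 cells (454 genes, 0.743 to 0.758). Over all genes, the root of the ratio of covariances between the siRNAs was 0.491 (0.452 to 0.515). Over the 5228 and 1338 genes called in the averaged comparisons, and so chosen on both siRNAs, the responses in siCYP1B1 cells had 0.957 times the size of those in scrambled cells for E2 (0.942 to 0.973 without any 1 library) and 1.06 times for 16aOHE (1.00 to 1.14).

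Many genes differed with siCYP1B1 although Cyp1b1 itself fell by 13.1%. GC content or transcript length bias was argued against, since 5329 genes were called after a correction for GC content and length against 5289 before, with 4738 shared. As a check for mislabelled libraries, 0 siCYP1B1 libraries had Cyp1b1 at or above a scrambled library of their arm. That repeats the level of Cyp1b1 reported above, was known before the check, and is no separate test. A candidate explanation is off-target pairing of the siRNA through its seed, because 1 sequence of 7 bases, AAAGTCA, marked the lower genes with z = -12.9, a size of 12.9 against 4.23 for the most extreme sequence with E2 and 6.35 with 16aOHE, and it ranked first in each arm. Among genes with a searched 3′ UTR it lay in that of 26.7% of those called lower, 9.0% of those called higher and 15.6% of those not called, and at 2 places in the 3′ UTR of Cyp1b1. The median shift was small (-0.027 with and 0.035 without the site) and 4332 called genes lacked it, so that the fall of Cyp1b1 and indirect effects stay open for most genes, and the siRNA sequence is not given in the sources used here.

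The mesothelial genes Msln, Upk3b and Wt1 were high and most endothelial markers near the floor in every library. A small admixture of another cell type in a mainly endothelial culture was argued against, as Pecam1, Vwf and Plvap did not exceed 0.384 CPM in any library. That argument holds only for endothelial cells that keep these 3 genes in culture, and it restates the same pattern. A candidate explanation is that cells other than the labelled type, of a mesothelial or fibroblast kind, made up most of the culture, since the lowest value of Msln, Upk3b or Wt1 in any library was 192 CPM and the median of 19 endothelial markers was 0.824 CPM. That comparison sets 3 chosen genes against a list. It restates the pattern that prompted it and is no separate test. The list medians were alike, 0.858 CPM for epithelial and mesothelial and 1.93 CPM for fibroblast markers. The first of these lists joins markers of epithelia to the 3 mesothelial genes, so that its median does not measure mesothelial markers alone. Cd34 (107 CPM) and Flt1 (70.0 CPM) were not near the floor. Loss of endothelial genes in culture stays open for the low endothelial markers. That loss alone would not account for Msln, Upk3b and Wt1, which reached at least 192 CPM in every library. No biological explanation was tested, as the design has 1 cell label.

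After removal of the group means, 1 component held 24.6% of the remaining variance and was highest in the first-listed library in 6 of 6 groups. Library depth cannot be told apart from other sources, because the correlation with log depth was r = -0.505 (Spearman's rho = -0.476, 2-sided permutation p = 0.22 for r) and was -0.241 without the 2 libraries farthest in depth. GC content or transcript length bias stays open as well, with a correlation of gene loadings with GC content of 0.154 and with length of 0.046. That the library with the highest score was the shallowest had been seen before the depth test. No biological explanation was tested, and the labels give no batch.

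Other splits of the libraries into groups of the same sizes were fitted for each count. For each averaged comparison 1 of 100 splits, the real one, reached the count: 5296 genes for siCYP1B1 (highest other 661), 5228 for E2 (1666) and 1338 for 16aOHE (64). That argues against a random assignment of single libraries to groups. It cannot exclude chance differences between cultures, because the labels do not say that the 3 libraries of a group were separate cultures. In each of the 9 pairwise comparisons 1 of 10 splits, the real one, reached the count, and 10 splits are too few for a share under 0.05. The real counts were 2437, 2506 and 2331 for siCYP1B1 in vehicle, E2 and 16aOHE (highest others 1, 1 and 0), 3548 and 3254 for E2, 454 and 639 for 16aOHE, and 2180 and 2171 for 16aOHE against E2 (highest others 0 in these 6).

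In the same scan of 3′ UTRs, the most extreme sequence for 16aOHE averaged over both siRNAs was ATTTATT, with z = 6.35.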
